A study of Homo sapiens with 24 samples.

How the data were processed

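The data are mRNA sequencing counts of 24 libraries from IMR90 fibroblasts that carry the RAS fusion, in 4 groups of 6 (Control, RIS, NIS and RNIS, as defined at the start of the report), collected on day 6 of 100 nM 4-OHT or vehicle per the labels. Each deposited file holds raw counts per Ensembl gene for 1 library, whole numbers with a different total in each. Libraries were made with a TruSeq kit, per the labels' protocols. The submitters' processing notes list TopHat2 2.0.4, HTSeq 0.5.3p9, DESeq 1.10.1 and GRCh37, without saying which step each served, and give no annotation release or strand setting. The last 5 lines of each file, which count reads assigned to no gene, carry the names that HTSeq writes. They were left out of library sizes and tests, and amount to between 18.1 and 28.4% of the reads in a library, counted over genes and these lines.

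Each file held 54127 genes, 36585 of which had a symbol in the reference table and 17542 did not. Of the 32317 genes with at least 1 count, 13933 passed edgeR's filterByExpr, 626 of them without a symbol. Counts were scaled by TMM and fitted with the quasi-likelihood model of edgeR 4.0.16 under R 4.3.3 (glmQLFit and glmQLFTest) with 1 mean per group and no covariate, all 24 libraries sharing a dispersion estimate (square root of the common dispersion 0.0915). P-values were adjusted by Benjamini-Hochberg over the genes tested, with a threshold of 0.05. The 7 contrasts were RIS, NIS and RNIS against Control, RNIS against RIS and NIS, NIS against RIS, and the interaction of the 2 factors. CPM use TMM-scaled library sizes, and log2 CPM for correlations and principal components a prior count of 2. The tested genes had a median of 6374 counts over the 24 libraries. Error terms of log2 changes are standard errors implied by the test, the size of the change over the square root of its F statistic. They are less certain where a group had few counts. Other error terms are SD between libraries. A lower bound on a fold, set by a floor of 3 counts over the group, covers counting error alone.

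For 25 lists of genes written from general knowledge, camera of limma 3.58.1 tested whether a list moved against the other genes, with its preset inter-gene correlation of 0.01. Its 175 p-values were adjusted together. Each call was repeated with a correlation estimated for the list, and with fry. A list needed at least 3 tested genes. In each list the counts higher and lower are those called over all genes, and again with adjustment over the list alone. The genes named are 27 chosen in advance; for each contrast the 5 largest rises and the 5 largest falls among called genes with a mean of at least 10 CPM in the higher group, a symbol and no overlap between the libraries compared; and for each list the 3 members with the smallest adjusted p and the first in the opposite direction. The overlap condition does not apply to the interaction. Some of these were left out of a paragraph, and a few are not reported here. Markers without enough counts for a test, and ESR1, were named after their values were seen. Groups, contrasts, tests, lists, the naming rule and the alternatives were fixed before the data were examined, apart from those the closing section names as chosen later.

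The share of RAS-responsive genes turned back in RNIS was measured with separate sets of 3 RIS libraries for choosing and testing. The method was tested on simulated data drawn from the means and library sizes of these libraries. In a simulation of RIS against Control over 13653 genes, it called 53 of 64 genes changed 1.5-fold (82.8%), 61 of 66 changed 2-fold (92.4%), 65 of 66 changed 4-fold (98.5%), and 10 of 13437 unchanged genes (0.0744%). For the interaction the shares were 67.2, 86.4 and 95.5%. With nothing changed between NIS and Control, 1 of 13653 genes was called. A simulated list of 20 changed genes was called by camera (adjusted p = 3.83e-79) and none of 20 unchanged lists. Few genes were changed in this simulation and genes were drawn independently, whereas 54.1 to 79.2% of genes were called in the data, depending on the contrast. It therefore does not test the scaling, or the preset correlation of the list tests, under changes as wide as those. Replicates were checked for duplicates: none of the 60 pairs within groups was identical, and chi-square per degree of freedom between replicates ran from 1.50 to 49.3.

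The alternatives tried were RLE and upper-quartile scaling, no filter beyond 1 count, a filter of 1 CPM in 6 libraries, a test against a fold of 1.5, DESeq2 1.42.0, limma voom, a fit of only the groups compared, thinning to the smallest library, the replicate number as a block, and leaving out each of the 24 libraries in turn. Library totals without scaling, the mitochondrial share as a covariate, and a division of the vector libraries by that share were added after the data were seen.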

Results

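Gene expression was measured by mRNA sequencing in IMR90 cells, an established line of human lung fibroblasts, that carried an oncogenic RAS fused to the estrogen receptor. The fusion is switched on by 4-hydroxytamoxifen (4-OHT). The cells had been transduced with a vector alone or with the FLAG-tagged intracellular domain of NOTCH1 (N1ICD), the active form of the receptor, and were then kept for 6 days with 100 nM 4-OHT or with vehicle. This gave 4 groups of 6 libraries: vector and vehicle (Control), vector and 4-OHT (RIS, for RAS-induced senescence), N1ICD and vehicle (NIS, for NOTCH-induced senescence), and N1ICD with 4-OHT (RNIS). The design text of the series states 6 biological replicates for each condition. The libraries held between 7.72 and 22.6 M counts in genes (M = 1e6), with a mean of 13.3 ± 2.57 (SD) M in Control, 11.8 ± 1.97 in RIS, 13.3 ± 5.08 in NIS and 13.2 ± 3.72 in RNIS. After the low-count filter 13933 genes were tested. Expression levels are given in CPM (counts scaled to 1e6 per library), as mean ± SD over the 6 libraries of a group. Log2 changes are given with the standard error implied by their test, n = 6 per group. The largest rises and falls are those of the fitted log2 change. Where a group had few or no counts this value rests on the prior count of the fit, so the order among such genes, and between them and genes with counts in both groups, is not settled. Adjusted p-values of single genes are from edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment over the genes tested.

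Libraries of the same group resembled each other closely, with Pearson correlations of log2 CPM between 0.987 and 0.995 across genes. The first principal component held 62.3% of the variance, the second 21.2% and the third 9.2%. The files of the vector libraries were numbered from 1 to 12 and those of the N1ICD libraries again from 1 to 12, and the labels do not say what the numbers stand for. If the sets were handled apart, that difference is part of each contrast between N1ICD and vector cells and cannot be told apart from N1ICD. Reads of the introduced genes were not counted apart, so the counts of the genes they derive from may hold endogenous and introduced transcripts together. NOTCH1 stood at 34.4 ± 5.27 CPM in Control and 51.5 ± 5.08 in RIS, against 256 ± 30.9 in NIS and 216 ± 29.6 in RNIS. Its rise in NIS over Control was 7.47-fold (log2 change 2.90 ± 0.103, adjusted p = 8.56e-22). HRAS reached 3102 ± 334 CPM in Control and 2660 ± 259 in RIS, and was lower with N1ICD, at 952 ± 105 in NIS (log2 change -1.71 ± 0.084, adjusted p = 5.60e-18) and 1382 ± 145 in RNIS. ESR1, the gene of the estrogen receptor, which was chosen after its values were seen, followed the same order, with 673 ± 38.2 CPM in Control, 580 ± 54.6 in RIS, 191 ± 17.7 in NIS and 274 ± 19.0 in RNIS. RNIS thus differed from RIS in the level of HRAS as well as in N1ICD, with HRAS lower by a log2 change of -0.95 ± 0.083 (adjusted p = 9.53e-12). As far as these counts hold the fusion, the level of the introduced RAS may have differed too.

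**Figure D1:**
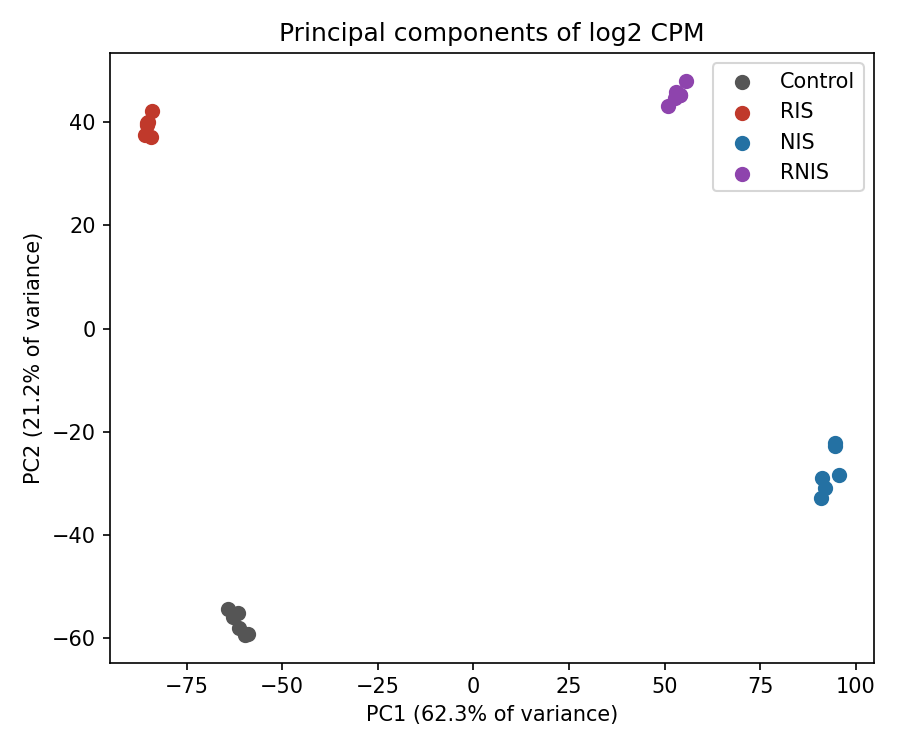
Principal components 1 and 2 of log2 CPM over the 13933 genes tested, in percent of variance on the axis labels (62.3% and 21.2%), with each point a library and the groups by colour. The 6 libraries of each group lie together and apart from those of the other groups.

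RIS was compared with Control to ask what RAS activation by 4-OHT did to the fibroblasts without N1ICD. No group received 4-OHT without the RAS fusion. An effect of 4-OHT itself thus cannot be told apart from RAS in any contrast between groups with and without it, the interaction included. All 36 cell cycle genes, 22 of 25 matrix genes and 12 of 14 contractile genes fell, and 11 of 16 cytokines and chemokines and the metalloproteinase genes MMP1, MMP3 and MMP10 rose. With an estimated correlation the cell cycle list alone of these 4 kept its call. MKI67, a marker of proliferation, dropped from 119 ± 14.5 to 7.14 ± 0.958 CPM (log2 change -4.06 ± 0.136, adjusted p = 5.86e-22). COL1A1, the main chain of type I collagen, dropped from 23520 ± 2410 to 2833 ± 273 CPM (log2 change -3.05 ± 0.082, adjusted p = 2.82e-24). MMP3, a stromelysin that degrades matrix proteins, rose 15.5-fold to 8749 ± 1010 CPM (log2 change 3.96 ± 0.157, adjusted p = 3.95e-20). IL1A, a cytokine that acts upstream of other inflammatory genes, rose 4.37-fold to 331 ± 24.3 CPM (log2 change 2.13 ± 0.069, adjusted p = 2.86e-22).

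Of the inflammatory cytokines and chemokines tested, 11 of 16 rose in RIS, 3 fell and 2 passed in neither direction (camera adjusted p = 0.0106, and adjusted p = 0.503 with an estimated correlation). CXCL5, a neutrophil chemokine, rose 20.5-fold, CCL20 8.88-fold and IL1B 8.06-fold to 8614 ± 250 CPM, while CXCL6 fell from 38.2 ± 10.8 to 13.1 ± 1.2 CPM. CXCL8 rose 1.32-fold from a high 5586 ± 1200 CPM (adjusted p = 0.0275), a call that DESeq2 did not make (adjusted p = 0.0760), and CXCL1 rose 1.57-fold. IL6 stood at 1041 ± 184 CPM in Control and 866 ± 34.8 in RIS and did not pass the test (log2 change -0.27 ± 0.144, adjusted p = 0.104). It was lower when the 12 libraries of these groups were fitted alone (adjusted p = 0.00710) and without the low-count filter (adjusted p = 1.06e-05). Among the matrix proteases and plasminogen genes 9 of 16 rose and 5 fell (camera adjusted p = 0.305). MMP1, the interstitial collagenase, rose 5.36-fold to 20270 ± 1640 CPM and MMP10 rose 8.04-fold, whereas SERPINE2 fell 2.60-fold. CEBPB, a transcription factor of the inflammatory secretome, rose 2.0-fold, and all 5 tested members of the C/EBP family rose, DDIT3 by 4.40-fold (camera adjusted p = 0.0125, and adjusted p = 0.101 with an estimated correlation). Of the NF-kappaB target genes 10 of 14 rose and 3 fell (camera adjusted p = 0.0945), with TRAF1 up 4.58-fold, TNFAIP3 up 2.18-fold and VCAM1 down 3.69-fold. RAS-MAPK feedback and output genes rose in 13 of 19 cases and fell in 2 (camera adjusted p = 3.62e-05, and adjusted p = 0.0359 with an estimated correlation), led by the MAP kinase phosphatases DUSP4 (12.8-fold) and DUSP5 (4.38-fold) and the feedback inhibitor SPRY2 (3.86-fold).

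All 36 cell cycle genes fell in RIS (camera adjusted p = 1.87e-20, and adjusted p = 0.00728 with an estimated correlation), among them the spindle checkpoint kinase BUB1 (12.9-fold), the mitotic motor KIF11 (11.3-fold), CCNA2 (12.3-fold) and the replicative helicase subunit MCM6 (7.95-fold). Of the CDK inhibitors and p53 target genes 15 of 20 rose and 3 fell (camera adjusted p = 0.00132, and adjusted p = 0.117 with an estimated correlation). CDKN2B rose 3.08-fold, CDKN2A, whose counts cover both p16 and ARF, 2.24-fold, CDKN1A 1.94-fold to 1270 ± 80.2 CPM, and the stress cytokine GDF15 10.3-fold, whereas CDKN1B fell 1.63-fold. The nuclear lamina and architectural chromatin list fell in 10 of 14 genes and rose in 2 (camera adjusted p = 0.00402, and adjusted p = 0.0814 with an estimated correlation). LMNB1, the lamin B1 gene, fell 8.04-fold and HMGB2 7.98-fold, while HMGA1 and HMGA2, which mark senescent heterochromatin, rose 1.45-fold and 1.32-fold.

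Collagens and other matrix genes fell in 22 of 25 cases and rose in 2 (camera adjusted p = 3.45e-11, and adjusted p = 0.145 with an estimated correlation), with COL3A1 down 12.8-fold, COL5A2 12.6-fold and COL1A2 9.73-fold, and TNC up 1.42-fold. Contractile and myofibroblast genes fell in 12 of 14 cases and rose in 1 (camera adjusted p = 3.46e-06, and adjusted p = 0.145 with an estimated correlation). ACTA2, the smooth muscle actin, fell 8.91-fold, TAGLN 6.42-fold, and the actin nucleator LMOD1 46.9-fold. TGF-beta ligands, latency proteins and SMAD targets fell in 13 of 17 cases and rose in 3 (camera adjusted p = 0.00206, and adjusted p = 0.183 with an estimated correlation). CCN2 fell 9.31-fold, TGFB2 3.81-fold and TGFBI 1.42-fold, while TGFB1 stood at 113 ± 22.7 CPM in Control and 97.0 ± 7.89 in RIS (adjusted p = 0.0644, and between 3.02e-04 and 0.0427 in 5 of the alternative fits). Of the secreted growth factors and IGF-binding proteins 9 of 21 rose and 11 fell (camera adjusted p = 0.830), FGF7 by 10.4-fold and IGFBP3 by 5.41-fold. Lysosomal genes rose in 14 of 20 cases and fell in 5 (camera adjusted p = 0.00645, and adjusted p = 0.338 with an estimated correlation), with the sialidase NEU1 up 2.45-fold. NOTCH target genes moved both ways, 3 of 11 higher and 3 lower (camera adjusted p = 0.910). HEY1 rose 3.62-fold and JAG1 2.81-fold, HES1 fell 1.98-fold and NOTCH3 4.49-fold.

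Among the largest rises in RIS, PI3, the elastase inhibitor elafin, rose from 0.136 ± 0.111 to 46.3 ± 4.61 CPM, LCE1F, a late cornified envelope gene, from 0.0528 ± 0.105 to 18.1 ± 3.13, IL36RN from 0.170 ± 0.106 to 43.1 ± 3.65, and SERPINB4 from 0.962 ± 0.578 to 184 ± 29.6. IVL, involucrin, rose from 0.0653 ± 0.0534 to 11.5 ± 1.07 CPM. The largest falls were in COL15A1 (51.9-fold), LMOD1, the fatty acid elongase ELOVL2 (35.6-fold), the hedgehog inhibitor HHIP (32.6-fold) and TNFSF4 (27.7-fold). In all, 4873 genes were higher and 4562 lower in RIS than in Control, 1147 and 1311 of them by more than 2-fold. Of the 13933 genes tested, 6604 had no overlap between the 6 libraries of each group, where chance gives 0.216% of genes. Adjusted over the list alone, the counts were the same except for 6 instead of 5 matrix protease genes lower, 14 instead of 13 TGF-beta genes lower, and 2 instead of 3 NOTCH targets lower. Scaled by library totals alone, 63.8% of the called genes were higher instead of 51.7%, with the median over all genes shifted from 0.03 to 0.16 on the log2 scale.

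NIS was compared with Control to ask what N1ICD did without RAS activation. All 16 cytokines and chemokines and all 36 cell cycle genes fell, and all 11 NOTCH targets, all 14 contractile genes and 17 of 25 matrix genes rose. With an estimated correlation the cell cycle and NOTCH target lists kept their calls and the other 3 did not. HEYL, a transcriptional repressor induced by NOTCH, rose 561-fold from 1.36 ± 0.417 to 758 ± 31.6 CPM (log2 change 9.13 ± 0.138, adjusted p = 3.27e-31). IL1A fell 151-fold from 75.6 ± 8.34 to 0.468 ± 0.186 CPM (log2 change -7.24 ± 0.133, adjusted p = 3.38e-29), and MKI67 fell from 119 ± 14.5 to 0.30 ± 0.0849 CPM (log2 change -8.59 ± 0.225, adjusted p = 2.81e-25). ACTA2 rose 17.1-fold to 2873 ± 320 CPM (log2 change 4.10 ± 0.109, adjusted p = 4.21e-25).

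All 11 NOTCH target genes rose (camera adjusted p = 6.10e-08, and adjusted p = 3.52e-04 with an estimated correlation). JAG1, itself a NOTCH ligand, rose 143-fold to 2164 ± 84.6 CPM, HEY1 48.8-fold, NOTCH3 12.8-fold and HES1 2.83-fold. The wider list of receptors, ligands and pathway components moved both ways, 10 of 21 higher and 8 lower (camera adjusted p = 0.499), with the ligand DLL4 down 10.1-fold. All 16 inflammatory cytokines and chemokines fell (camera adjusted p = 8.36e-10, and adjusted p = 0.101 with an estimated correlation). CXCL8 fell 69.1-fold, IL6 25.7-fold to 40.7 ± 14.9 CPM, IL11 26.4-fold, CXCL1 23.0-fold, IL1B 11.4-fold, and CSF2, the granulocyte-macrophage colony-stimulating factor, 255-fold. Matrix proteases and plasminogen genes fell in 10 of 16 cases and rose in 4 (camera adjusted p = 0.0164, and adjusted p = 0.257 with an estimated correlation). MMP3 fell 95.6-fold, MMP1 30.4-fold, SERPINB2 39.5-fold and the urokinase gene PLAU 13.2-fold, whereas the protease inhibitor TIMP3 rose 4.44-fold. NF-kappaB targets fell in 9 of 14 cases and rose in 4 (camera adjusted p = 0.0755), with BIRC3 down 54.7-fold and NFKBIA down 3.11-fold but IRF1 up 2.15-fold. In the C/EBP family 4 of 5 genes fell and none rose (camera adjusted p = 0.0632), CEBPD by 9.32-fold and CEBPB by 1.76-fold.

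All 36 cell cycle genes fell in NIS (camera adjusted p = 1.59e-20, and adjusted p = 0.00728 with an estimated correlation), including the ribonucleotide reductase subunit RRM2 (238-fold), the topoisomerase TOP2A (198-fold) and the checkpoint kinase BUB1B (305-fold). CDK inhibitors and p53 targets rose in 16 of 20 cases and fell in 1 (camera adjusted p = 1.61e-04, and adjusted p = 0.0836 with an estimated correlation). CDKN2B, the p15 gene, rose 65.8-fold to 939 ± 66.6 CPM, CDKN2A 9.29-fold, BTG2 6.10-fold and CDKN1A 1.48-fold, while GDF15 fell 2.79-fold. Lamina and architectural chromatin genes fell in 12 of 14 cases and rose in 2 (camera adjusted p = 1.80e-05, and adjusted p = 0.00966 with an estimated correlation). HMGA2 fell 36.0-fold, HMGA1 31.4-fold from 455 ± 66.2 to 14.6 ± 1.60 CPM, and LMNB1 23.6-fold, and LMNA rose 1.44-fold.

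Contractile and myofibroblast genes rose in all 14 cases (camera adjusted p = 9.80e-08, and adjusted p = 0.101 with an estimated correlation), MYH11, the smooth muscle myosin heavy chain, from 1.28 ± 0.432 to 872 ± 93.4 CPM and CALD1 by 6.60-fold. Matrix genes rose in 17 of 25 cases and fell in 6 (camera adjusted p = 8.96e-04, and adjusted p = 0.499 with an estimated correlation). POSTN rose 24.7-fold, BGN 17.4-fold, SPARC 4.95-fold, COL3A1 4.57-fold and COL1A1 1.56-fold to 36660 ± 3070 CPM, while DCN fell 3.58-fold. Among TGF-beta ligands, latency proteins and SMAD targets 11 of 17 rose and 5 fell (camera adjusted p = 0.0973). TGFB3 rose 12.9-fold, TGFB2 9.05-fold, CCN2 5.15-fold and TGFB1 2.66-fold, and TGFBI fell 1.39-fold. Cholesterol synthesis genes rose in 15 of 16 cases and fell in 1 (camera adjusted p = 1.79e-04, and adjusted p = 0.0617 with an estimated correlation), with HMGCS1, an early enzyme of the pathway, up 2.85-fold. Antigen presentation genes rose in 10 of 12 cases and fell in none (camera adjusted p = 6.75e-04, and adjusted p = 0.117 with an estimated correlation), TAP1, the peptide transporter, by 2.92-fold. Growth factors and IGF-binding proteins fell in 14 of 21 cases and rose in 6 (camera adjusted p = 0.0164, and adjusted p = 0.253 with an estimated correlation). HGF fell 207-fold and VEGFC 7.71-fold, and HBEGF rose 8.91-fold. Hypoxia and glycolysis genes fell in 11 of 14 cases and rose in 3 (camera adjusted p = 0.0289, and adjusted p = 0.483 with an estimated correlation), with ADM down 5.57-fold and the glucose transporter gene SLC2A1 up 3.43-fold. The fibroblast and mesenchymal markers divided, 5 of 10 higher and 5 lower (camera adjusted p = 0.987). PDGFRB rose 6.01-fold and PDGFRA fell 12.6-fold.

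Among the largest rises in NIS were GUCY1A1, a subunit of the nitric oxide receptor, from no count in any Control library to 44.3 ± 3.48 CPM (at least 1208-fold higher, with 3 counts over the Control group as the floor), GJA4, connexin 37, from 0.0228 ± 0.0364 to 86.5 ± 8.07 CPM, and OR51E1 from 0.0946 ± 0.0895 to 242 ± 9.08. SH2D3C rose from 0.0137 ± 0.0336 to 44.3 ± 5.26 CPM, and TNN, tenascin N, which had no count in Control, was at least 531-fold higher at 19.0 ± 3.94 CPM, a bound that does not settle its rank. The largest falls were in STC1, stanniocalcin, which fell 503-fold from 2411 ± 248 CPM, in CSF3 (333-fold), BUB1B and MKI67, and in TROAP, from 11.1 ± 2.12 to 0.0214 ± 0.0339 CPM. In all, 5131 genes were higher and 5042 lower, 1786 and 1767 of them by more than 2-fold. Of the 13933 genes tested, 7426 had no overlap between the groups. The counts of the lists were the same when adjusted over the list alone. The 10 most abundant genes took 16.2 ± 0.903% of the counts in NIS and 9.49 ± 0.329% in Control, and scaled by library totals alone 29.9% of called genes were higher instead of 50.4%, with 3195 genes higher and the median over all genes shifted from 0.01 to -0.27.

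**Figure D2:**
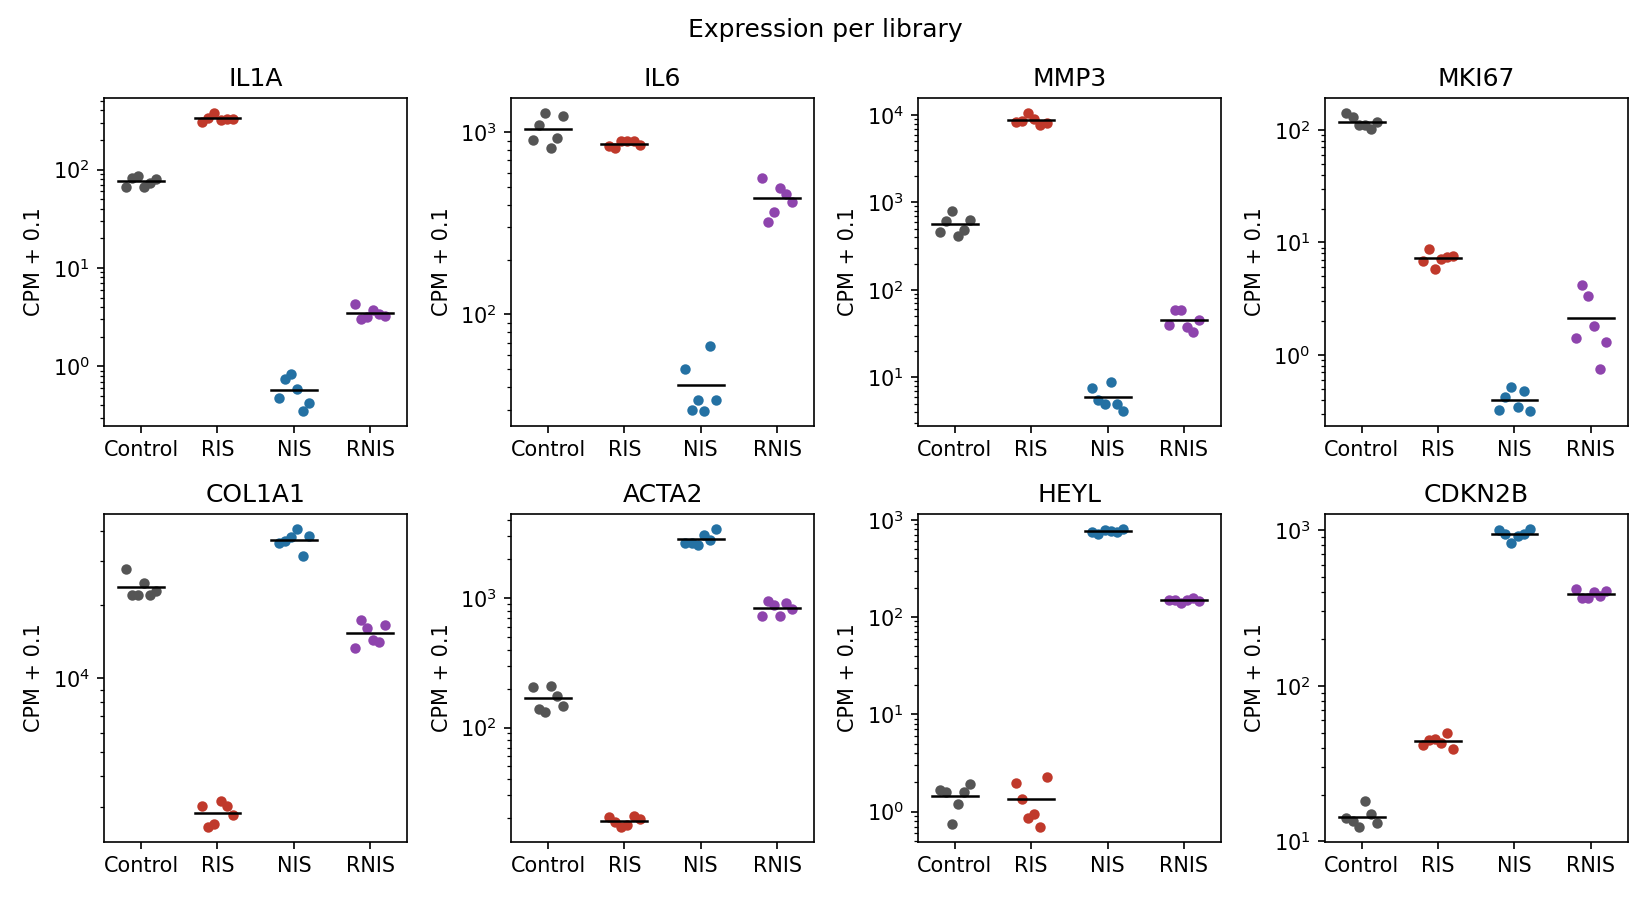
Expression per library of IL1A, IL6, MMP3, MKI67, COL1A1, ACTA2, HEYL and CDKN2B, in CPM plus 0.1 on a log axis, by group. Points are the 6 libraries of each group and bars the group means. IL1A lies at 331 CPM on average in RIS and at 0.468 and 3.37 in NIS and RNIS, and ACTA2 at 18.8 in RIS and 842 in RNIS.

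RNIS was compared with RIS to ask what N1ICD did to cells with activated RAS. This contrast also lies across the separate numbering of vector and N1ICD libraries. All 11 NOTCH targets, 19 of 25 matrix genes and 13 of 14 contractile genes were higher, and 15 of 16 inflammatory genes lower, than with RAS alone. With an estimated correlation the NOTCH targets alone of these 4 lists kept their call. IL1A fell 96.7-fold, from 331 ± 24.3 to 3.37 ± 0.459 CPM (log2 change -6.60 ± 0.095, adjusted p = 1.24e-31), a level below that of Control (75.6 ± 8.34). ACTA2 rose 44.7-fold to 842 ± 95.8 CPM (log2 change 5.48 ± 0.120, adjusted p = 3.24e-27), and COL1A1 rose 5.39-fold to 15270 ± 1570 CPM (log2 change 2.43 ± 0.080, adjusted p = 1.49e-22). HRAS was lower in RNIS, as given above.

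Of the inflammatory cytokines and chemokines 15 of 16 fell and 1 rose (camera adjusted p = 6.07e-06, and adjusted p = 0.205 with an estimated correlation). CCL20 fell 388-fold, CSF2 15.1-fold, CXCL1 6.18-fold, CXCL8 3.10-fold and IL6 1.99-fold, IL1B fell 1.82-fold and stayed at 4725 ± 191 CPM, and CCL2, a monocyte chemokine, rose 3.80-fold. Matrix proteases fell in 11 of 16 cases and rose in 5 (camera adjusted p = 0.0270, and adjusted p = 0.297 with an estimated correlation). MMP3 fell 193-fold, PLAU 5.90-fold, SERPINE2 5.01-fold and MMP1 2.02-fold, and TIMP3 rose 14.8-fold. All 5 tested C/EBP genes fell (camera adjusted p = 0.0139, and adjusted p = 0.104 with an estimated correlation), CEBPD by 9.55-fold and CEBPB by 1.74-fold. NF-kappaB targets fell in 9 of 14 cases and rose in 3 (camera adjusted p = 0.0541), with BIRC3 down 18.4-fold and TRAF1 5.89-fold. RAS-MAPK feedback and output genes fell in 13 of 19 cases and rose in 4 (camera adjusted p = 0.00564, and adjusted p = 0.124 with an estimated correlation), DUSP4 by 18.7-fold and SPRY2 by 5.74-fold, while MYC rose 1.58-fold. Growth factors and IGF-binding proteins fell in 14 of 21 cases and rose in 6 (camera adjusted p = 0.0172, and adjusted p = 0.255 with an estimated correlation), HGF by 474-fold and NRG1 by 25.4-fold, while HBEGF rose 7.17-fold. Lysosomal genes fell in 14 of 20 cases and rose in 3 (camera adjusted p = 0.0210, and adjusted p = 0.434 with an estimated correlation), with CTSB, cathepsin B, down 2.27-fold.

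All 11 NOTCH targets rose in RNIS (camera adjusted p = 3.87e-08, and adjusted p = 3.52e-04 with an estimated correlation), HEYL 122-fold, JAG1 28.3-fold, HEY1 10.3-fold and HES1 5.23-fold. Contractile genes rose in 13 of 14 cases (camera adjusted p = 6.61e-08, and adjusted p = 0.101 with an estimated correlation), TAGLN by 15.3-fold and TPM1 by 6.53-fold. Matrix genes rose in 19 of 25 cases and fell in 4 (camera adjusted p = 5.46e-07, and adjusted p = 0.271 with an estimated correlation), with SPARC up 10.6-fold, COL3A1 9.64-fold and BGN 8.05-fold, and TNC down 2.61-fold. CCN2 rose 27.1-fold and TGFB2 18.6-fold, and 10 of 17 TGF-beta genes rose and 5 fell (camera adjusted p = 0.190). Cholesterol synthesis genes rose in 13 of 16 cases and fell in 2 (camera adjusted p = 8.13e-04, and adjusted p = 0.0836 with an estimated correlation), INSIG1 by 3.32-fold. Cell cycle genes, already low in RIS, fell further in 23 of 36 cases and rose in 2 (camera adjusted p = 0.00491, and adjusted p = 0.368 with an estimated correlation). MKI67 fell 3.36-fold and MCM6 rose 2.98-fold. CDKN2B rose 8.88-fold and CDKN2A 3.31-fold, GDF15 fell 9.54-fold, and CDKN1A, at 1308 ± 105 CPM, did not differ by more than its error (log2 change 0.04 ± 0.065, adjusted p = 0.567). Among the CDK inhibitors and p53 targets as a list 8 of 20 rose and 8 fell (camera adjusted p = 0.953). HMGA1 fell 12.6-fold and LMNB1 1.84-fold.

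Of the genes named for their rise in RIS, SERPINB4 fell 717-fold to 0.223 ± 0.152 CPM, LCE1F to 0.0387 ± 0.063 and IVL to 0.287 ± 0.155 in RNIS, whereas PI3 fell from 46.3 ± 4.61 to 15.5 ± 4.79 CPM and IL36RN from 43.1 ± 3.65 to 29.1 ± 5.58. LCE2C fell at least 419-fold to no count in RNIS, and the salivary cystatins CST1 and CST4 fell from 144 ± 15.8 to 0.0207 ± 0.0329 and from 39.8 ± 2.78 to 0.0121 ± 0.0297 CPM. CSF3, the granulocyte colony-stimulating factor, fell 732-fold. Among the largest rises were the homeobox gene GBX2 (921-fold), OR51E1 (867-fold), FOXS1, from 0.0116 ± 0.0284 to 27.9 ± 2.44 CPM, GJA4 and the carbonic anhydrase gene CA4, from 0.0116 ± 0.0284 to 22.2 ± 3.27 CPM. In all, 4998 genes were higher and 5336 lower, 1800 and 1546 by more than 2-fold. Adjusted over the list alone, 14 instead of 13 contractile genes rose and the other counts were the same. Scaled by library totals alone, 38.3% of called genes were higher instead of 48.4%, with the median over all genes shifted from -0.02 to -0.15.

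To ask what share of the RAS response was turned back in RNIS, genes were chosen on RIS replicates 1 to 3 and measured against RIS replicates 4 to 6. No library thus entered both differences. Both were tested in a single fit of all 24 libraries with shared estimates of spread, so the steps are not fully independent. Of 4277 genes higher in the first RIS libraries than in Control, 2419 were lower in RNIS than in the other RIS libraries (56.6%, exact Clopper-Pearson 95% interval 55.1 to 58.0%), against 35.6% of all genes tested, and 726 were higher still. Of 4071 genes lowered by RAS, 2069 were higher in RNIS (50.8%, interval 49.3 to 52.4%), against 33.0% of all genes, and 984 were lower still. The intervals treat genes as independent, which they are not. HRAS was also lower in RNIS than in RIS, so these shares cannot be credited to N1ICD alone. A gene lower in RNIS than in RIS need not have returned to its level in Control.

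RNIS was compared with NIS to ask what RAS activation did in cells that carried N1ICD. Of the inflammatory genes 14 of 16 and of the cell cycle genes 33 of 36 were higher, and 21 of 25 matrix, 13 of 14 contractile and all 12 antigen presentation genes lower. None of these 5 lists kept its call with an estimated correlation. MMP1 rose 80.8-fold from 124 ± 32.3 to 10040 ± 1050 CPM (log2 change 6.34 ± 0.141, adjusted p = 8.40e-26), IL1B 50.4-fold from 94.0 ± 35.4 to 4725 ± 191 CPM (log2 change 5.66 ± 0.184, adjusted p = 5.04e-22), and HEYL fell 5.12-fold from 758 ± 31.6 to 148 ± 6.00 CPM (log2 change -2.36 ± 0.089, adjusted p = 2.07e-20).

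Of the inflammatory list 14 of 16 rose and none fell (camera adjusted p = 1.35e-09, and adjusted p = 0.101 with an estimated correlation), with CSF2 up 31.6-fold, CXCL8 29.4-fold, IL6 10.7-fold and IL1A 6.83-fold, and 11 of the 16 genes remained lower in RNIS than in Control. RAS-MAPK genes rose in 11 of 19 cases and fell in 4 (camera adjusted p = 0.00419, and adjusted p = 0.117 with an estimated correlation), DUSP5 by 6.18-fold and DUSP6 by 4.16-fold, while the ephrin receptor gene EPHA4 fell 9.89-fold. The epidermal growth factor family member EREG rose 15.2-fold and SERPINB2 52.2-fold. Cell cycle genes rose in 33 of 36 cases (camera adjusted p = 7.14e-09, and adjusted p = 0.0850 with an estimated correlation), RRM2 by 7.97-fold, MKI67 by 6.87-fold and MCM2 by 2.70-fold, and all 36 remained lower than in Control. HMGA2 rose 7.55-fold and HMGA1 3.61-fold, and 8 of 14 lamina and chromatin genes rose and 1 fell (camera adjusted p = 0.0411, and adjusted p = 0.183 with an estimated correlation). Matrix genes fell in 21 of 25 cases and rose in 1 (camera adjusted p = 1.35e-09, and adjusted p = 0.183 with an estimated correlation), the elastin gene ELN by 76.2-fold and COL3A1 by 6.10-fold. Contractile genes fell in 13 of 14 cases and rose in 1 (camera adjusted p = 1.74e-06, and adjusted p = 0.135 with an estimated correlation), MYH11 by 32.6-fold and ACTA2 by 3.41-fold, and TGF-beta genes fell in 15 of 17 cases and rose in 2 (camera adjusted p = 3.32e-05, and adjusted p = 0.0892 with an estimated correlation), TGFB3 by 5.51-fold and TGFB1 by 1.90-fold. All 12 antigen presentation genes fell (camera adjusted p = 3.32e-05, and adjusted p = 0.0814 with an estimated correlation), the immunoproteasome subunit PSMB9 by 3.69-fold and HLA-C by 1.86-fold. Interferon-stimulated genes fell in 11 of 19 cases and rose in 1 (camera adjusted p = 0.0392, and adjusted p = 0.271 with an estimated correlation), IFIT1 by 3.57-fold. NOTCH1 itself fell 1.18-fold (adjusted p = 0.0219), a call lost with upper-quartile scaling (adjusted p = 0.119) and, with a log2 change of 0.03, with library totals alone. CDK inhibitors and p53 targets fell in 14 of 20 cases and rose in 4 (camera adjusted p = 0.0127, and adjusted p = 0.207 with an estimated correlation), and 4 of 5 C/EBP genes rose (camera adjusted p = 0.0270, and adjusted p = 0.136 with an estimated correlation). Of the NOTCH targets 7 of 11 fell and 2 rose (camera adjusted p = 0.0973), with JAG1 down 1.80-fold and HES2 up 5.18-fold.

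Among the largest rises were IL36RN (347-fold), IL36B, from 0.0214 ± 0.0339 to 11.6 ± 1.68 CPM, PI3, from 0.0336 ± 0.0545 to 15.5 ± 4.79 CPM, the receptor kinase ROS1 (198-fold) and MGAT4C (183-fold). The largest falls were in ELN, the delta globin gene HBD (69.0-fold), the chloride channel ANO1 (47.2-fold), PRRX2 (46.5-fold) and OLFML2A (45.6-fold). In all, 4632 genes were higher and 4628 lower, 1209 and 1038 by more than 2-fold. Adjusted over the list alone, 15 instead of 14 inflammatory genes rose, 15 instead of 14 CDK inhibitor and p53 genes fell, and the counts of the other lists given here were the same. Scaled by library totals alone 7622 genes were higher and 2531 lower, 75.1% higher instead of 50.0%, with the median over all genes shifted from 0.01 to 0.29.

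RNIS was also set against Control, to show where cells with both inducers ended. Lamina and chromatin genes were lower in 13 of 14 cases and higher in 1 (camera adjusted p = 2.71e-05, and adjusted p = 0.0106 with an estimated correlation). All 36 cell cycle genes were lower than in Control (camera adjusted p = 1.43e-18, and adjusted p = 0.00966 with an estimated correlation), TOP2A by 45.2-fold and MKI67 by 56.1-fold, and all 11 NOTCH targets higher (camera adjusted p = 6.10e-08, and adjusted p = 3.52e-04 with an estimated correlation). CDK inhibitors and p53 targets were higher in 12 of 20 cases and lower in 3 (camera adjusted p = 0.0337, and adjusted p = 0.296 with an estimated correlation). CDKN2B was 27.4-fold higher (log2 change 4.77 ± 0.081, adjusted p = 7.88e-30), CDKN2A 7.42-fold and GADD45A 3.96-fold, while DDB2 was 1.74-fold lower. The inflammatory list was divided, with 11 of 16 lower and 4 higher (camera adjusted p = 0.0115, and adjusted p = 0.510 with an estimated correlation). IL1A was 22.1-fold lower, IL24 11.6-fold lower and IL6 2.39-fold lower, and IL1B 4.42-fold higher. Matrix proteases were lower in 9 of 16 cases and higher in 6 (camera adjusted p = 0.182), MMP3 12.5-fold lower and MMP1 2.66-fold higher. MMP9, a gelatinase, rose from 0.0811 ± 0.106 CPM in Control, 3.23 ± 0.961 in RIS and 1.72 ± 0.785 in NIS to 258 ± 93.4 in RNIS. The RAS-MAPK list had 8 of 19 genes higher and 8 lower (camera adjusted p = 0.909), DUSP5 4.95-fold higher and ETV1 8.58-fold lower. Contractile genes were higher in 11 of 14 cases and lower in 2 (camera adjusted p = 0.00215, and adjusted p = 0.331 with an estimated correlation), ACTA2 by 5.02-fold, whereas matrix genes were higher in 8 of 25 and lower in 15 (camera adjusted p = 0.326), POSTN 16.3-fold higher and DCN 9.42-fold lower. Cholesterol synthesis genes were higher in 14 of 16 cases and lower in none (camera adjusted p = 3.98e-05, and adjusted p = 0.0359 with an estimated correlation), INSIG1 by 4.89-fold. In the unfolded protein and integrated stress response list 6 of 12 genes were higher and 4 lower (camera adjusted p = 0.909), with the chaperone gene HSPA5 1.97-fold lower. Growth factors and IGF-binding proteins were lower in 14 of 21 cases and higher in 5 (camera adjusted p = 0.0103, and adjusted p = 0.205 with an estimated correlation). The largest falls were in HGF (693-fold), EDNRB, from 28.2 ± 2.96 to 0.0227 ± 0.0367 CPM, SFRP1 (195-fold), NPTX1 (188-fold) and TRPA1 (163-fold). Beside MMP9 the rises in GJA4 and CA4 were among the largest by the fit, as were those in GUCY1A1 and the pseudogene OR7E19P, at least 401-fold and 403-fold higher than Control groups with no count, bounds that do not settle their rank. In all, 5329 genes were higher and 4975 lower, 1774 and 1652 by more than 2-fold. The counts of these lists did not change when adjusted over the list alone.

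The direct contrast of NIS with RIS set the transcripts of the 2 single inducers against each other. All 16 inflammatory genes were lower in NIS (camera adjusted p = 5.17e-09, and adjusted p = 0.114 with an estimated correlation), IL1A by 661-fold (log2 change -9.37 ± 0.126, adjusted p = 1.64e-32), CSF2 by 476-fold and CXCL8 by 91.0-fold. Matrix proteases were lower in 10 of 16 cases and higher in 4 (camera adjusted p = 0.0420, and adjusted p = 0.338 with an estimated correlation). MMP3 was 1482-fold lower, MMP1 163-fold and SERPINB2 332-fold, and TIMP3 10.6-fold higher. Matrix genes were higher in 22 of 25 cases and lower in 2 (camera adjusted p = 1.42e-09, and adjusted p = 0.184 with an estimated correlation), COL3A1 by 58.8-fold and SPARC by 25.2-fold, and all 14 contractile genes were higher (camera adjusted p = 3.87e-08, and adjusted p = 0.0990 with an estimated correlation), ACTA2 by 153-fold and LMOD1 by 297-fold. TGF-beta genes were higher in 11 of 17 cases and lower in 4 (camera adjusted p = 0.0108, and adjusted p = 0.257 with an estimated correlation), with TGFB2 34.4-fold and TGFB1 3.09-fold higher, while TGFBI, at 3083 ± 185 CPM in NIS and 3023 ± 185 in RIS, did not pass (adjusted p = 0.664) and had a log2 change of -0.39 with library totals alone. RAS-MAPK genes were lower in 16 of 19 cases and higher in 2 (camera adjusted p = 4.07e-05, and adjusted p = 0.0359 with an estimated correlation), DUSP4 by 33.5-fold. Cell cycle genes were lower in 32 of 36 cases and higher in 2 (camera adjusted p = 3.59e-07, and adjusted p = 0.117 with an estimated correlation), MKI67 by 23.1-fold. NOTCH targets were higher in 10 of 11 cases (camera adjusted p = 1.81e-06, and adjusted p = 0.00124 with an estimated correlation). Camera also called antigen presentation genes (11 of 12 higher, 1 lower) and cholesterol synthesis genes (12 of 16 higher, 2 lower), and NF-kappaB targets (11 of 14 lower, 3 higher), C/EBP genes (5 of 5 lower), lamina and chromatin genes (10 of 14 lower, 2 higher) and lysosomal genes (15 of 20 lower, 2 higher). None of these 6 kept its call with an estimated correlation. Among the largest differences were SEMA5B, at least 1544-fold higher in NIS than in RIS, PLXDC1 (1778-fold), OR51E1 (2200-fold), FOXS1 and GJA4. Lower in NIS were BCL2A1, CST4 and TAGLN3, at least 1198-fold, 886-fold and 879-fold, SERPINB4 (2649-fold) and CSF3 (2546-fold). In all, 5306 genes were higher and 5733 lower in NIS, 2222 and 2201 by more than 2-fold. Counts adjusted over the list alone were the same. Scaled by library totals alone 3228 genes were higher in NIS, 27.5% of those called instead of 48.1%, with the median over all genes shifted from -0.03 to -0.45.

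**Figure D3:**
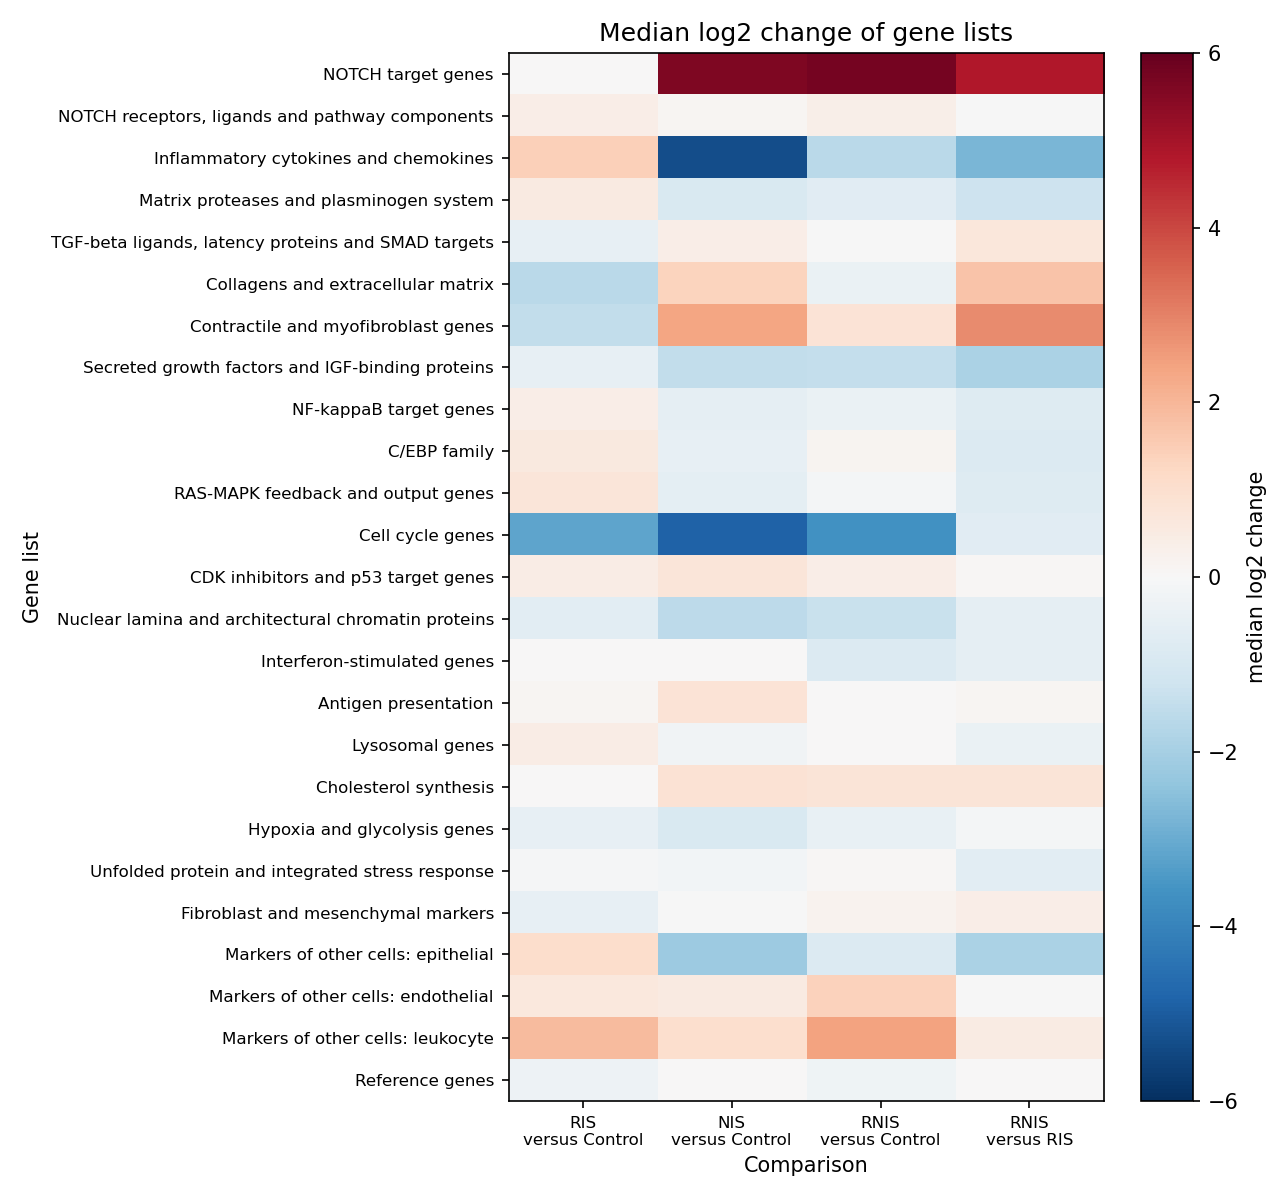
Median log2 change of each gene list fixed before the data were examined, for RIS, NIS and RNIS against Control and RNIS against RIS, on a colour scale from -6 to 6. Cell cycle genes have medians of -3.17, -4.84 and -3.65 against Control, and inflammatory genes of 1.41 in RIS and -5.34 in NIS.

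The interaction of the factorial design asked whether the effect of RAS differed with N1ICD, a positive value meaning a higher RAS effect in N1ICD cells. Since HRAS was lower in N1ICD cells, the effects compared may also differ in the level of RAS. In all, 3689 genes had a positive and 3854 a negative interaction. All 36 cell cycle genes had a positive one (camera adjusted p = 1.35e-29, and adjusted p = 0.00140 with an estimated correlation). MKI67 fell by 4.06 on the log2 scale with RAS in vector cells and rose 6.87-fold with RAS in N1ICD cells, an interaction of 6.84 ± 0.400 (adjusted p = 2.46e-15), and MYBL2 (7.32 ± 0.462), KIF20A (7.03 ± 0.428) and BUB1 (5.31 ± 0.177) behaved alike. These rises began at low levels, with MYBL2 at 0.186 and KIF20A at 0.114 CPM in NIS. MKI67 reached 2.02 CPM in RNIS, below RIS (7.14) and Control (119). All 36 genes were lower than Control in RIS, NIS and RNIS. A positive interaction here thus shows that the 2 falls did not add up, and not a return to the level of Control. Lamina and chromatin genes were positive in 12 of 14 cases and negative in 1 (camera adjusted p = 2.01e-06, and adjusted p = 0.00616 with an estimated correlation), LMNB1 by 3.68 ± 0.160. Inflammatory genes were positive in 14 of 16 cases (camera adjusted p = 2.53e-05, and adjusted p = 0.246 with an estimated correlation), CCL2 by 4.58 ± 0.242, CXCL8 by 4.48 ± 0.236 and IL6 by 3.69 ± 0.216, and IL1A by 0.64 ± 0.236 (adjusted p = 0.0220, and 0.0744 with limma voom). CDK inhibitors and p53 targets were negative in 18 of 20 cases (camera adjusted p = 1.05e-07, and adjusted p = 0.0144 with an estimated correlation), CDKN2B by -2.89 ± 0.102 and BTG2 by -2.72 ± 0.131. Hypoxia and glycolysis genes were positive in 11 of 14 cases and negative in 2 (camera adjusted p = 0.00272, and adjusted p = 0.297 with an estimated correlation), and matrix genes in 14 and 6 of 25 (camera adjusted p = 0.0164, and adjusted p = 0.591 with an estimated correlation). Antigen presentation genes were negative in 10 of 12 cases (camera adjusted p = 2.66e-05, and adjusted p = 0.0793 with an estimated correlation), PSMB8 by -1.81 ± 0.105. The largest negative values included THBD, thrombomodulin, which reached 115 ± 4.13 CPM in RIS and 2.29 ± 0.477 in RNIS (-7.21 ± 0.146, adjusted p = 3.96e-26), and MAP2, at 32.5 ± 5.31 CPM in NIS and 1.17 ± 0.335 in RNIS (-7.00 ± 0.281). Adjusted over the list alone, 11 instead of 10 antigen presentation genes were negative, 7 instead of 6 matrix genes were negative and 1 CDK inhibitor or p53 target was positive. With library totals alone 65.3% of called genes were positive instead of 48.9%, with the median over all genes shifted from -0.02 to 0.13.

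Across the 13933 genes, the N1ICD effect in RAS-activated cells correlated with that in vehicle cells with Pearson r = 0.751 (Spearman 0.684), and of 8095 genes called in both, 86.7% moved the same way. Both were higher for 3516 genes and both lower for 3505, where independent lists would share 1841 and 1931. The RAS effect with N1ICD correlated less with that without it, r = 0.434 (Spearman 0.427), with 75.9% of 6779 genes called in both moving the same way. The effects in each pair share no library, and genes are not independent replicates. Both N1ICD effects lie across the separate numbering of vector and N1ICD libraries, whereas each RAS effect lies within a set. A difference in handling, if there was any, would enter both N1ICD effects alike and could raise their agreement. The higher correlation therefore cannot be credited to N1ICD alone.

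Of the epithelial markers KRT5 had no count in any library and EPCAM reached at most 0.722 CPM on average. Among the 3 tested, KRT15 rose from 3.41 ± 0.696 to 7.21 ± 0.703 CPM and CLDN4 from 1.92 ± 0.498 to 4.61 ± 1.02 in RIS (list camera adjusted p = 0.391). Among the 4 endothelial markers tested TIE1 rose 17.2-fold in RIS to 14.2 ± 1.60 CPM and TEK fell 4.09-fold from 127 ± 9.10 (camera adjusted p = 0.643). Of the 3 leukocyte markers LAPTM5 rose 34.6-fold in RIS to 8.77 ± 1.2 CPM while PTPRC, CD45, stayed at or under 0.117 CPM on average in every group (camera adjusted p = 0.185). In RNIS all 3 leukocyte markers tested were higher than in Control and than in NIS (camera adjusted p = 0.0566 and 0.0525), CORO1A reaching 7.08 ± 0.955 CPM. Of the endothelial markers 3 of 4 were higher and 1 lower in RNIS than in Control (camera adjusted p = 0.484). In NIS the epithelial marker CDH1 was 9.49-fold higher than in Control, at 1.17 ± 0.267 CPM, and the other 2 tested were lower (camera adjusted p = 0.546). Fibroblast and mesenchymal markers fell in 7 of 10 cases and rose in 1 in RIS (camera adjusted p = 0.00634, and adjusted p = 0.0793 with an estimated correlation), TCF21 by 7.48-fold. Hypoxia and glycolysis genes fell in 10 of 14 cases in RIS and rose in 1 (camera adjusted p = 0.0487, and adjusted p = 0.522 with an estimated correlation), SLC2A1 by 2.87-fold while HK2 rose 2.20-fold. In the stress response list 5 of 12 genes rose and 5 fell in RIS (camera adjusted p = 0.718), TRIB3 rising 4.84-fold and CHAC1 falling 1.93-fold. Interferon-stimulated genes rose in 3 of 19 cases and fell in 7 (camera adjusted p = 0.570), OAS3 by 1.94-fold. Antigen presentation and cholesterol synthesis genes moved both ways in RIS, 4 of 12 and 6 of 16 higher with 3 lower in each (camera adjusted p = 0.499 for both), and the NOTCH pathway components rose in 13 of 21 cases and fell in 7 (camera adjusted p = 0.465). Adjusted over the list alone, 6 instead of 5 stress response genes and 2 instead of 3 antigen presentation genes fell, and the other counts were the same. Of the 10 reference genes 7 were lower in RIS and none higher (camera adjusted p = 0.0877), ACTB by 1.44-fold. The self-contained test fry, which asks whether the genes of a list move on balance one way and not whether they differ from other genes, called 152 of the 175 list tests, camera with its preset correlation 76 and camera with an estimated correlation 15. Those 15 were NOTCH targets in NIS and RNIS against Control and against RIS, cell cycle and lamina genes, RAS-MAPK genes in RIS against Control and in NIS against RIS, cholesterol synthesis genes in RNIS against Control, and CDK inhibitors in the interaction. The cell cycle calls held in all 3 groups against Control and in the interaction, and the lamina calls in NIS and RNIS against Control and in the interaction. Reads were counted per gene with those shared between copies left unassigned, so that levels of multigene families such as HLA, LCE, SERPINB, cystatin and globin genes are uncertain. Strand use is not stated in the labels, so overlaps with antisense genes are uncertain too.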

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

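The 3 tests of why inflammatory genes were lower in RNIS than in RIS, given last in this part, were chosen after that result was seen, and the others were planned. For 7 measures of the libraries and the genes of the text, 688 groups of 6 libraries were examined. Of these, 43 had a library far from the other 5 by Dixon's test. For normally distributed values chance gives about 1 in 20 groups, or 34. Where 5 libraries had no count, any count in the other passes this test, and a group without counts cannot be flagged. Thus 43 against 34 does not show an excess of outlying libraries. RNIS library 5 had the largest share of reads in no gene, 7.1% against 3.89 to 4.67% in the other RNIS libraries, and of reads not placed uniquely, 18.1% against 15.4 to 16.2%, and a mitochondrial share of 3.07% against 1.14 to 1.73%. The other 40 are CPM of single genes, given with the range of the other 5 libraries. In Control these were CHAC1 at 119 (88.6 to 97.9), HMGA2 at 904 (1040 to 1100), SH2D3C at 0.0822 (0 to 0), SLC2A1 at 450 (348 to 374), TRPA1 at 376 (428 to 451) in library 1, ROS1 at 0.366 (0.0822 to 0.175) in library 4, CA4 at 0.0714 (0 to 0) in library 5, FOXS1 at 0.349 (0 to 0.11), LCE1F at 0.262 (0 to 0.0549) in library 6. In RIS these were HMGB2 at 4.35 (5.76 to 6.54) in library 1, CA4 at 0.0696 (0 to 0), FOXS1 at 0.0696 (0 to 0), MYC at 55.8 (65 to 70.1) in library 3, IRF1 at 49.6 (55.5 to 58.5) in library 4, DDIT3 at 85.4 (48.9 to 60.5), GADD45A at 167 (79 to 102), HES1 at 6.45 (3.33 to 4.38), JAG1 at 52.8 (38.3 to 42.6), NRG1 at 577 (650 to 673), OR7E19P at 0.0742 (0 to 0), SERPINB2 at 2140 (2600 to 2740), SH2D3C at 0.222 (0 to 0) in library 5, CCL2 at 18 (10.6 to 13) in library 6. In NIS these were ROS1 at 0.3 (0 to 0.109) in library 1, GBX2 at 99.9 (113 to 117), HMGCS1 at 126 (89.9 to 102), IVL at 0.0536 (0 to 0) in library 2, LCE2C at 0.104 (0 to 0) in library 3, LCE1F at 0.12 (0 to 0) in library 4, HBEGF at 333 (284 to 299), NOTCH3 at 1550 (1800 to 1910), SPARC at 22500 (25300 to 26300) in library 5, CLDN4 at 1.2 (0.12 to 0.428) in library 6. In RNIS these were EPHA4 at 4.16 (2.62 to 3.09), LMNB1 at 4.99 (3.08 to 3.66), NPTX1 at 1.32 (0.34 to 0.655) in library 2, CST4 at 0.0728 (0 to 0), VEGFC at 53.4 (47.1 to 48) in library 3, TAGLN at 1380 (1210 to 1270), TGFB2 at 320 (380 to 400) in library 5.

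The effect of RAS differed with N1ICD, by the interaction test, for 25 of the 26 genes chosen in advance and reported here. HRAS was lower in N1ICD cells, so a difference in the level of RAS cannot be told apart from N1ICD here. HRAS and NOTCH1, which are among the 25, may hold counts of the introduced genes. The log2 difference was positive for MKI67 (6.84), CXCL8 (4.48), CCNA2 (4.32), MMP1 (3.92), IL6 (3.69), LMNB1 (3.68), IL1B (2.65), CXCL1 (1.90), COL1A1 (1.79), ACTA2 (1.39), HMGA1 (1.31), TGFBI (1.31), COL3A1 (1.07), HES1 (0.89), HRAS (0.76) and IL1A (0.64). It was negative for CDKN2B (-2.89), JAG1 (-2.34), HEY1 (-2.24), HEYL (-2.20), CDKN2A (-1.49), MMP3 (-1.01), NOTCH1 (-0.83), TGFB1 (-0.71) and CDKN1A (-0.52). Among gene lists, 7 differed by camera, with median log2 differences for inflammatory genes (2.57), matrix genes (0.48), cell cycle genes (4.53), CDK inhibitors and p53 targets (-0.89), lamina and chromatin genes (0.98), antigen presentation genes (-0.71) and hypoxia and glycolysis genes (0.98), and the cell cycle, lamina and CDK inhibitor lists also with an estimated correlation. In all 7 comparisons 1 of 60 splits of the libraries, the real one, reached the number of genes called. Most other splits mix groups that lie apart, which widens the spread within groups, and they called few or no genes. The splits therefore show only that the groups lie apart, and not what sets them apart. The real number and the highest of the others were 9435 and 6167 for RIS against Control, 10173 and 7302 for NIS, 10304 and 7326 for RNIS, 10334 and 7448 for RNIS against RIS, 9260 and 5979 for RNIS against NIS, 11039 and 8387 for NIS against RIS, and 7543 and 508 for the interaction.

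Reads assigned to no gene, which no comparison uses, also differed from Control, by exact permutation tests of the mean adjusted over 9 tests. The share outside genes was 4.04 ± 0.119% (SD, n = 6) in RIS and 4.67 ± 1.23% in RNIS against 3.54 ± 0.152% in Control (exact permutation test, adjusted p = 0.00389 for both). Reads in overlapping genes took 3.16 ± 0.0203% in RIS, 3.05 ± 0.0613% in NIS and 3.09 ± 0.0562% in RNIS against 2.93 ± 0.048% in Control (exact permutation test, adjusted p = 0.00389, 0.00649 and 0.00389). Reads not placed uniquely took 17.9 ± 0.505% in RIS and 12.7 ± 0.727% in NIS against 16.6 ± 0.575% in Control (exact permutation test, adjusted p = 0.0111 and 0.00389). The share outside genes in NIS, 3.72 ± 0.55%, and that not placed uniquely in RNIS, 16.1 ± 0.989%, did not pass (exact permutation test, adjusted p = 0.584 and 0.363). No explanation for these shares was tested.

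The inflammatory genes were lower in RNIS than in RIS, as was HRAS, whose counts may hold the RAS fusion. The choice among TMM, RLE, upper-quartile and no scaling did not account for the lower inflammatory genes. The list's median log2 change was -2.73 at its nearest to 0, with 15 of 16 genes lower under each. Over all genes these scalings moved the median only between -0.15 and 0.004, so a list this far from 0 was bound to stay low. A scaling error beyond that range was not tested. Weaker RAS signalling stays open as a part of the cause: the median of the RAS-MAPK list was -0.79 in RNIS against RIS, with camera adjusted p = 0.00564 and adjusted p = 0.124 with an estimated correlation. As the whole cause it cannot be told apart either, because 11 of 16 inflammatory genes were lower in RNIS than in Control while 8 RAS-MAPK genes were higher and 8 lower than in Control, which leaves the level of RAS output undecided. An effect of N1ICD on these genes, which fell in NIS without 4-OHT, may add to it. NIS does not set this apart from RAS output, since HRAS was lower there too (952 against 3102 CPM in Control). Of the RAS-MAPK genes 11 of 19 were lower and 7 higher in NIS than in Control (median log2 change -0.61, camera adjusted p = 0.0776, and adjusted p = 0.331 with an estimated correlation). A difference in handling between vector and N1ICD libraries, which carried separate sets of file numbers, was not tested and stays open too.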

How the results depend on the processing

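The fits with library totals alone, with the mitochondrial share, and of the vector libraries divided by that share were chosen after the data were seen. The numbers of genes higher and lower stayed within 1.5 times those reported under RLE and upper-quartile scaling, both filters, thinning, DESeq2, voom, the fit of only the groups compared and the fit with the mitochondrial share as a covariate. That share was 0.857 ± 0.279% in Control, 1.03 ± 0.452% in RIS, 1.15 ± 0.332% in NIS and 1.69 ± 0.706% in RNIS, and with it as a covariate 2 calls of named genes changed, TGFB1 in RIS (adjusted p = 0.00598) and CEBPB in RNIS against Control (adjusted p = 0.139). With library totals alone, higher genes were 3195 in NIS against Control, 7622 in RNIS against NIS (2531 lower) and 3228 in NIS against RIS, and log2 changes reversed to 0.03 for NOTCH1 in RNIS against NIS and -0.39 for TGFBI in NIS against RIS, because scaling sets the 0. Tested against a fold of 1.5, a stricter test by construction, genes higher and lower were 1530 and 1712 in RIS against Control, 2254 and 2197 in NIS, 2256 and 2203 in RNIS, 2297 and 2160 in RNIS against RIS, 1501 and 1467 in RNIS against NIS, 2845 and 2915 in NIS against RIS, and 1430 and 1066 for the interaction. Of 175 list tests 76 were called, 15 with an estimated correlation and 152 with fry, which turned the direction of the RAS-MAPK list in RNIS against Control (adjusted p = 0.00125) and of the hypoxia list in RNIS against RIS (adjusted p = 0.00271). The cause was not tested. The agreement of the N1ICD effects was 0.537 without the filter and 0.814 over genes called in both contrasts, and that of the RAS effects 0.262 and 0.537. Of the RAS-induced genes, 54.65% were lower in RNIS than in RIS with the sets of RIS libraries exchanged, and 58.3% with all RIS libraries in both steps. Of the RAS-repressed genes, 52.96% were higher in RNIS than in RIS with all. Leaving out each library in turn gave 4396 to 4953 higher and 4441 to 4899 lower in RIS against Control, 4823 to 5199 and 4964 to 5241 in NIS, 5198 to 5431 and 4843 to 5101 in RNIS, 4917 to 5364 and 4906 to 5362 in RNIS against RIS, 4493 to 4917 and 4372 to 4645 in RNIS against NIS, 5316 to 5477 and 5558 to 5805 in NIS against RIS, and 3616 to 4177 and 3215 to 3889 for the interaction. The replicate number as a block moved no count by over 1.5 times, and residual correlations between libraries of the same number lay between -0.444 and 0.264 over 36 pairs, 3 above 0.1, so the numbers were not used as pairs. Vector libraries above 1% mitochondrial share gave 3707 genes higher and 3843 lower in RIS, and those below it 4326 and 4309. Of these, 7212 and 8282 were called as in all libraries and 0 opposite. Each set is a part of all libraries, so opposite calls were hardly possible, and the sets were not compared with each other.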

Other observations

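Every test below was chosen after the results were seen, and the lists of further genes were written after the patterns were seen, while the rule that a member needed 1 CPM or more on average in the reference group was set after the values of the members were seen. P-values of these lists were adjusted only over the lists of this section tested in the same way, and not with the 175 list tests above. LCE1F and IVL, genes of the cornified envelope, were among the largest rises in RIS. Keratinocytes that express the basal keratin genes KRT5 and KRT14, mixed into the RIS cultures, are argued against. These genes had 0 counts in the 6 RIS libraries, a limit of 0.0422 CPM at 3 counts over the unscaled total of the group. SERPINB4 reached 184 ± 29.6 CPM. KRT15, an epithelial marker, was higher in RIS (7.21 against 3.41 CPM in Control). No other keratin gene was examined, so keratinocytes without KRT5 and KRT14 stay open. Whether a wider cornified envelope programme rose could not be tested. Of 38 further genes of the envelope 6 had enough counts for a test, and 0 of these had 1 CPM or more in Control. A gene near 0 in Control enters the test by its rise and could not be seen to fall. With all 6 the median log2 change was 4.94 and adjusted p = 0.0196 with an estimated correlation, an outcome that this filter favours, and 5 rose and none fell. TGM1, the transglutaminase that links the envelope, did not pass (log2 change -0.28 ± 0.229, adjusted p = 0.357). Single envelope genes were thus transcribed in RIS, IVL at 11.5 and LCE1F at 18.1 CPM, and how far a programme beyond them rose stays open, because 0 members could be tested without this limit.

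GUCY1A1 and FOXS1, which pericytes express, were among the largest rises with N1ICD. A difference in handling between vector and N1ICD libraries, whose files carried separate sets of numbers, was not tested. Of 17 further mural cell genes 9 had 1 CPM or more in Control. Of these 8 rose and 1 fell in NIS, the same when adjusted over the list alone (median log2 change 3.27, camera adjusted p = 3.61e-04, and adjusted p = 0.0214 with an estimated correlation). In RNIS against RIS 7 had 1 CPM or more in RIS, and 5 rose and 2 fell, again the same over the list alone (median log2 change 1.82). The list did not pass there (camera adjusted p = 0.0676, and adjusted p = 0.197 with an estimated correlation). With all 13 members that had enough counts, those near 0 in the reference group included, adjusted p with an estimated correlation was 0.00673 and 0.0196. MCAM, an adhesion molecule of pericytes, rose from 156 to 3450 CPM in NIS (log2 change 4.46 ± 0.068, adjusted p = 3.52e-31), and CSPG4, the proteoglycan NG2, from 180 to 1830 CPM. GUCY1B1, which forms the nitric oxide receptor with the product of GUCY1A1, rose from 1.02 to 187 CPM, and the potassium channel gene KCNJ8 from 2.55 to 24.4 CPM. The aminopeptidase gene ANPEP fell from 237 to 34.1 CPM, and RGS5 was higher in NIS and lower in RNIS than in RIS (log2 change -3.64 ± 0.188). Without RAS activation N1ICD may have raised part of a mural cell programme. The camera test with an estimated correlation gave p = 0.0107, and adjusted p = 0.0214 over the lists of this section alone. That value was not adjusted with the 175 list tests above, so it cannot be set beside their adjusted p-values. With RAS activation a wider programme stays open, because few members were expressed in RIS and they moved in both directions. Many of these genes are also expressed by contractile fibroblasts, and whether a few cells or all carried them was not tested.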
